A study of Mus musculus with 19 samples.

How the data were processed

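RNA was measured in 19 libraries from mice of 12 weeks of age, 1 library per mouse. The design text describes separate animals, so the replicates are biological. There were 5 libraries of wild-type colon, 7 of colon tumours from mice with 1 Apc allele deleted in the gut epithelium (Apc tumour), and 7 of colon tumours from mice that were also labelled null for Tgif1 and Tgif2 (Apc/Tgif tumour). Villin-Cre, a recombinase active in intestinal epithelium, was used for the deletions. Libraries were poly-A selected and sequenced as single-end reads of 75 bases, per the labels' protocols. Whether the counting used strand is not given in the sources used here, so a gene and an overlapping antisense partner cannot be told apart.

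The deposited table holds 32694 gene symbols and 1 column of normalized counts per library, a signal that the authors made from counts per gene and a factor per library. Salmon and DESeq2 are named in the submitters' processing notes, with the GRCm38 and mm10 names of the mouse build, and their versions and the annotation are not given in the sources used here. The values themselves bear the marks of division by a size factor: the median ratio of each library to the geometric mean of all libraries lay between 1.00441 and 1.00454, and the values were not whole. In each library most low values were multiples of 1 step, the worth of 1 count, which lay between 0.743 and 1.44. Between 82.0% and 84.8% of the low values came out whole within a tolerance of 0.1 of a step, so whole reads were not recovered and no count model was used. The design fixed before the data were examined named a count test, with a test of log values as its substitute for a table of normalized values, and that substitute was used throughout.

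Totals of normalized counts lay between 34417808 and 44732717 per library. Divided by the step, they correspond to about 28700000 to 49100000 counts per library. This estimate is approximate. A normalized count of 10 thus stands for roughly 10 reads, and the depth limits the precision of values near it.

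Genes were tested where at least 5 libraries reached a normalized count of 10, which left 18445 genes. The test was limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with an intensity trend in the prior variance and robust empirical Bayes moderation, and all 19 libraries entered 1 fit with terms for group and sex. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05, and tests were two-sided. Every adjusted p of a single gene below comes from this limma fit. Fold changes are on the log2(normalized count + 1) scale and understate the change of low genes. Because the table holds no counts, no fold is given against a group listed at 0. Sex differences of an effect were tested as the effect in males minus the effect in females in a fit with 1 mean per group and sex.

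Of 42 gene lists fixed from textbook knowledge before the data were examined, 41 had measured members. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Counts of changed members are given over all genes tested and adjusted over the list alone. Named genes followed a rule fixed before the data were examined: the targeted genes, the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 100 normalized counts whose groups did not overlap, up to 4 members with the smallest p in each described list (here 2), the sex-linked genes, and the 3 smallest p of each sex interaction. Where fewer than 6 genes had groups that did not overlap, that condition was dropped. Some genes that this rule selects are not reported here. Which lists are described with members was chosen after the list results were seen. Predicted genes, clone names and immunoglobulin variable segments were left out of the naming, and 3233 of the tested names were of these kinds.

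Positions are from the GENCODE annotation of GRCm38 and were matched by symbol for 15983 of the tested genes. GC content and transcript length were available for 86.7% of the tested genes. Defensins, mast cell proteases and other families of near-identical copies share reads, so their single values are uncertain.

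The steps were tested on simulated data drawn from the means and spreads of the real genes, with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. For Apc tumours against wild-type colon, 51 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were recovered. For Apc/Tgif tumours against wild-type colon these were 54 and 83, and for Apc/Tgif against Apc tumours 60 and 91. False calls made up 7.33%, 9.27% and 5.62% of the calls, in that order, above the nominal 5%. These fits tested 18279, 18244 and 18271 simulated genes. For the sex interaction between the tumours, 13 of 100 genes changed 2-fold and 46 of 100 changed 4-fold were recovered. Far fewer genes were changed than were called in the data, and the simulated libraries had no shared trends. The recovered and false shares therefore cannot be carried over to the real comparisons.

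Alternatives fixed in advance were a pseudocount of 0.5 or 5, no filter beyond a total of 10, a filter of 1 CPM in 10 libraries, quantile normalization, no sex term, only the compared groups, each sex alone, each library left out, a smooth muscle score as covariate, and only changes over 2-fold. Others were added after seeing the data: equal totals, removal of each library's trend on GC content and transcript length, the distal colon score as covariate, library quality weights, means per group and sex, and removal of 3 libraries high in Rn45s. These 3 were wild-type replicates 2 and 4 and Apc/Tgif tumour replicate 5, and their removal left 1 male wild-type library. The smooth muscle score was centred within each group, so that setting could not remove the muscle difference between tumours and wild-type colon. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.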

Results

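Gene expression was compared among wild-type mouse colon, colon tumours of mice lacking 1 allele of Apc, the tumour suppressor that restrains Wnt signalling, and colon tumours of mice also labelled as lacking Tgif1 and Tgif2, a pair of related homeodomain repressors. Wild-type colon was taken from 3 female and 2 male mice, and each tumour group from 3 females and 4 males. Library totals lay between 34417808 and 44732717 normalized counts, which correspond to about 28700000 to 49100000 counts. Pearson's r between replicates, across genes, lay between 0.965 and 0.983 in wild-type colon, between 0.943 and 0.984 in Apc tumours and between 0.935 and 0.985 in Apc/Tgif tumours. Genes are not independent replicates, so these values describe the libraries only. The first principal component, with 53.5% of the variance, parted tumours from wild-type colon, and the second, with 10.5%, parted the tumour genotypes.

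**Figure D1:**
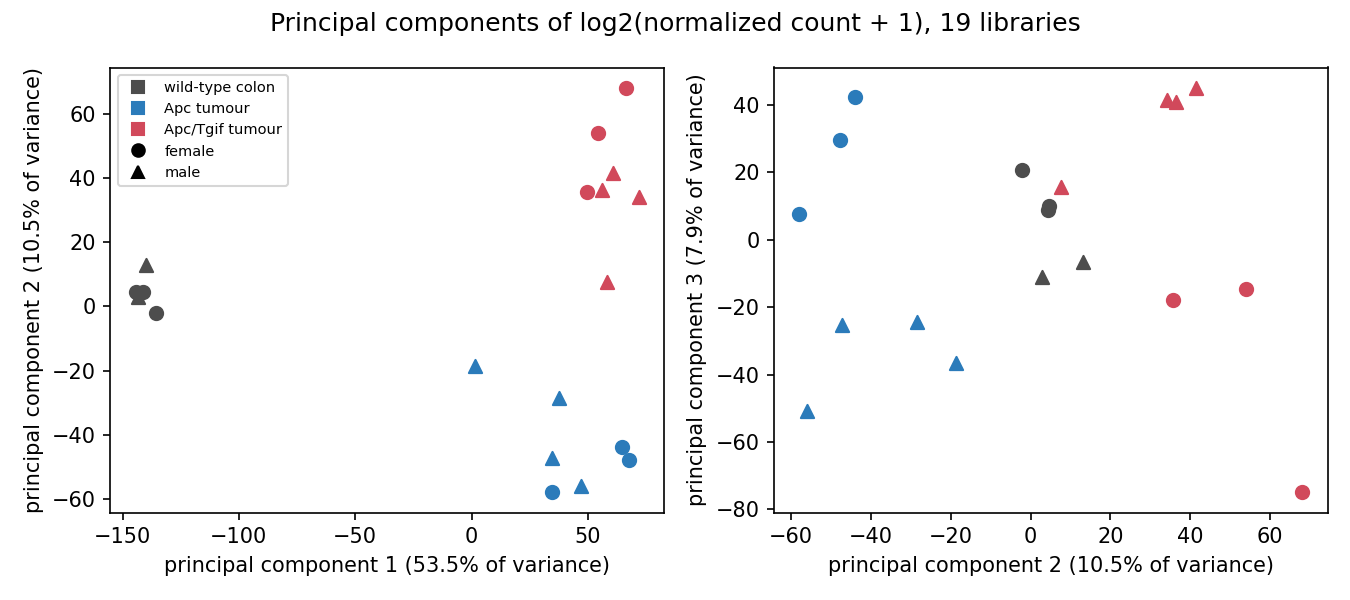
Principal components 1 and 2 (left) and 2 and 3 (right) of log2(normalized count + 1) in 19 libraries, with colour for group and symbol shape for sex; each point is 1 library. Wild-type libraries sit apart on component 1, which holds 53.5% of the variance, and the tumour genotypes part on component 2, which holds 10.5%.

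The targeted genes were examined first. Tgif1 (chromosome 17, 70844205 to 70853546, GRCm38) had 964 ± 143 normalized counts in wild-type colon (SD, n = 5), 3815 ± 803 in Apc tumours (SD, n = 7) and 354 ± 137 in tumours labelled Apc/Tgif (SD, n = 7). It fell by 3.47 on the log2 scale between the tumour genotypes (SE 0.165, limma adjusted p = 2.54e-10), and the highest value among the 7 tumours labelled Apc/Tgif, 654, lay below the lowest of the Apc tumours, 2785. Tgif2 (chromosome 2, 156840007 to 156855570) went against its label at the level of the whole gene: 161 ± 50.1 in wild-type colon, 642 ± 92.1 in Apc tumours and 2657 ± 352 in tumours labelled Apc/Tgif, a rise of 2.05 between the tumour genotypes (SE 0.158, limma adjusted p = 1.14e-07). The deleted part of either gene is not given in the sources used here, and reads from outside it would still count, so the total of Tgif2 does not check the deletion. Every direction given below for Apc/Tgif tumours rests on that label. Apc (chromosome 18, 34220924 to 34322552) had 5771 ± 1340, 6334 ± 1070 and 7272 ± 1190 normalized counts in the 3 groups, and none of its differences passed the threshold in the fit used here (limma adjusted p = 0.363, 0.0501 and 0.378). Its rise of 0.37 in Apc/Tgif tumours over wild-type colon lay at the threshold and passed in 12 other settings. These were a filter of 1 CPM (0.37), quantile normalization (0.43), leaving out wild-type replicate 1 (0.47), Apc tumour replicate 1 or 4 (0.38 each) or Apc/Tgif tumour replicate 2 or 5 (0.40 and 0.45), equal library totals (0.53), the distal colon covariate (0.44), quality weights (0.52), means per group and sex (0.39), and removal of the GC content and length trend (0.41). The trend was removed in the 15983 genes with both values known, and a fit of these genes alone already passed for this rise. With the trend removed the other 2 differences passed too (0.22 for Apc tumours over wild-type colon and 0.19 between the tumours), so whether Apc differs depends on the setting. The same label of 1 deleted Apc allele applies to both tumour groups.

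**Figure D2:**
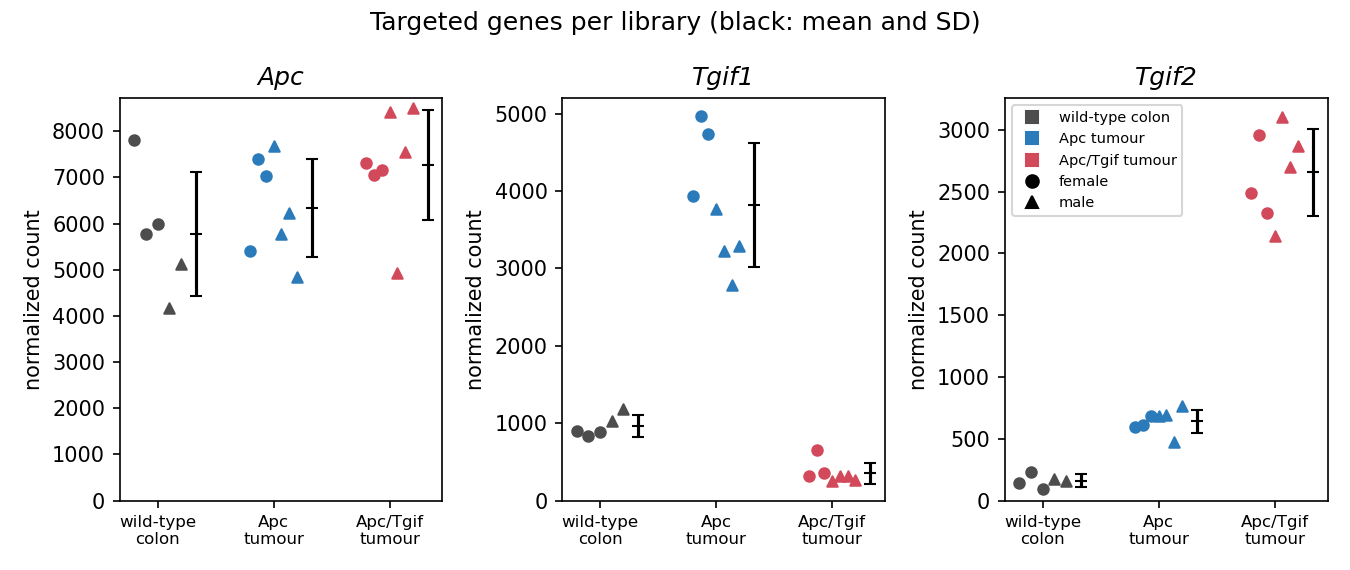
Normalized counts of Apc, Tgif1 and Tgif2 in each library, with the mean and SD of each group in black, colour for group and symbol shape for sex. Tgif1 is lowest in the 7 tumours labelled Apc/Tgif, at up to 654, while Tgif2 is highest in them, at a mean of 2657.

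Sex labels matched the sex-linked genes in all 19 libraries. Xist lay between 19659 and 39232 normalized counts in the 9 female libraries and between 4.27 and 79.95 in the 10 male ones. Ddx3y lay between 3.33 and 20.69 in females and between 1069 and 2748 in males.

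The first comparison asked how Apc tumours differ from wild-type colon. The lists of Wnt targets, stem cell genes, Paneth cell genes and neutrophil genes were called as higher in the tumours, and those of smooth muscle, enteric neurons, B cells, colonocytes and goblet cells as lower. With an estimated correlation the Paneth cell, B cell, colonocyte and goblet cell lists were no longer called. Mmp7, a metalloproteinase of Paneth cells, had 6.18 ± 2.32 normalized counts in wild-type colon (SD, n = 5) and 22890 ± 13300 in Apc tumours (SD, n = 7), a rise of 11.52 on the log2 scale (SE 0.469, limma adjusted p = 1.48e-12). Mptx1, a mucosal pentraxin, went from 102300 ± 35500 to 554 ± 595 and fell by 8.84 (SE 0.957, limma adjusted p = 4.69e-07). In all, 4415 genes were higher and 4639 lower among 18445 tested, and with library totals made equal, a setting added after seeing the data, these were 6160 and 3417.

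Among the highest genes were further Paneth cell products. Defa17 and Habp2 were listed at 0 in all 5 wild-type libraries and had means of 3981 and 1440 normalized counts in Apc tumours. Defa24 had a mean of 3004 in the tumours and was above 0 in only 1 wild-type library. Alpha-defensin genes are near-identical copies, so reads could be shared among them. S100a8, a calcium-binding protein of neutrophils, rose from 3.38 ± 4.77 to 2694 ± 916, and Reg3b, an antimicrobial lectin, from 2.44 ± 1.92 to 5255 ± 6950. Among the lowest genes, Pln, a muscle calcium pump regulator, went from 648 to 6.65 and Vip, a neuropeptide of enteric neurons, from 1553 to 29.1. The B cell genes Ighd and Fcmr went from 1212 to 11.5 and from 396 to 3.17, and Slc30a10, a manganese transporter, from 1156 to 19.1.

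Of 25 Wnt targets, 24 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.1e-14, and adjusted p = 0.037 with an estimated correlation). Notum, a secreted Wnt inhibitor, rose from 9.76 ± 7.14 to 5012 ± 2030. Of 17 stem cell and crypt base genes 14 rose and 3 fell, both over all genes and adjusted over the list alone (camera adjusted p = 6.3e-05, and adjusted p = 0.037 with an estimated correlation). Sox4 went from 966 to 9182 and Lgr5 from 438 to 4217. Of 13 Paneth cell genes 10 rose and 2 fell, both over all genes and adjusted over the list alone (camera adjusted p = 3e-06), with adjusted p = 0.2 with an estimated correlation. Of 23 neutrophil genes 22 rose and 1 fell, as they did adjusted over the list alone (camera adjusted p = 4.8e-15, and adjusted p = 0.037 with an estimated correlation). Cxcl3 went from 0.456 to 509 and S100a9 from 4.55 to 3421.

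Of 20 smooth muscle genes 19 fell, and 20 did adjusted over the list alone (camera adjusted p = 7.9e-18, and adjusted p = 0.037 with an estimated correlation). Mylk went from 23110 to 2890 and Smtn from 6535 to 1133. Wild-type colon thus carried more muscle and nerve transcripts than the tumours, beside every difference of this comparison. All 16 measured B and plasma cell genes fell, also adjusted over the list alone (camera adjusted p = 2.3e-08), with adjusted p = 0.16 with an estimated correlation, and Spib went from 846 to 33.2 and Ms4a1 from 708 to 15.1. Of 26 colonocyte genes 19 fell and 2 rose, both over all genes and adjusted over the list alone (camera adjusted p = 9.6e-06), with adjusted p = 0.26 with an estimated correlation. Car4, a carbonic anhydrase, went from 61160 to 1837 and Slc37a2 from 13650 to 438. Pan-epithelial genes fell too, by a smaller median of -0.522. Of 16 such genes 9 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.48 with an estimated correlation). Of 20 goblet cell genes 11 fell and 1 rose, both over all genes and adjusted over the list alone (camera adjusted p = 0.001), with adjusted p = 0.47 with an estimated correlation, and Klk1 went from 37710 to 4751 and Creb3l1 from 9564 to 2878. Of 31 fatty acid oxidation genes 24 fell and 2 rose, both over all genes and adjusted over the list alone (camera adjusted p = 3.9e-06), with adjusted p = 0.16 with an estimated correlation, and Slc25a20 went from 8064 to 3191 and Acad11 from 5537 to 1872.

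Of 26 interferon-stimulated genes 17 fell, and 17 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0013), with adjusted p = 0.57 with an estimated correlation. That call was lost in females alone, where the median went from -1.46 to -0.392. The list's score lay at 11.26 and 11.42 in the male wild-type libraries, between 8.63 and 9.88 in the female ones, and between 8.82 and 9.89 in female Apc tumours. The median interaction with sex was -3.15 (camera adjusted p = 8.5e-29), with adjusted p = 0.17 with an estimated correlation. Of 18 protease genes 16 rose, also adjusted over the list alone (camera adjusted p = 1.5e-12). Of 20 enteric neuron and glia genes 19 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 2.9e-10).

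Camera called 26 of the 41 lists, 12 higher and 14 lower, and 6 of them held with an estimated correlation. Besides those given above, these were the enteric neuron and protease lists (adjusted p = 0.037 and 0.041 with that correlation). Fry called 33 lists, and the median, the mean and the test differed in sign for 3. Random splits of the same 12 libraries called up to 33 lists, so the number of lists called does not stand out from other splits, whereas no other split called as many genes. Distal colon genes were not called as a list (camera adjusted p = 0.12), although Hoxb13 went from 14700 ± 1390 to 4679 ± 3500. The call of Hoxb13 was lost in males alone.

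The second comparison set Apc/Tgif tumours against wild-type colon. The lists of Wnt targets and Paneth cell genes were again called as higher and those of colonocytes and goblet cells as lower. Of these, only the Wnt target list was still called with an estimated correlation. Slc26a3, the chloride and bicarbonate exchanger of colonocytes, went from 62570 ± 19300 (SD, n = 5) to 175 ± 151 (SD, n = 7) and fell by 8.97 (SE 0.609, limma adjusted p = 9.26e-10). Mmp7 had 30360 ± 26000 normalized counts in these tumours and rose by 11.92 (SE 0.469, limma adjusted p = 6.42e-13). There were 4576 genes higher and 4708 lower, or 5810 and 3843 with equal totals.

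Cyp2c55, a cytochrome P450 with close paralogs, went from 16080 to 48.9 and Aqp8, a water channel, from 28070 to 128. Slc30a10 and Mptx1 reached 2.41 and 230, and Car4 reached 278. Defa17 and Defa20 were listed at 0 in all 5 wild-type libraries and had means of 2480 and 1850 in the tumours. Defa2, Defa22 and the protease inhibitor Serpinb11 had wild-type means of 0.690, 0.252 and 0.828 and tumour means of 2615, 1743 and 1962.

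Of 25 Wnt targets 24 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 1.9e-14, and adjusted p = 0.036 with an estimated correlation), and Notum reached 6821 ± 2600. Of 13 Paneth cell genes 10 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 5.9e-05), with adjusted p = 0.27 with an estimated correlation. Of 26 colonocyte genes 22 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 1.1e-08), with adjusted p = 0.17 with an estimated correlation, and Slc37a2 reached 285. The mean log2 score of the pan-epithelial list was also lower, at 14.01 ± 0.155 (SD, n = 7) against 14.52 ± 0.11 in wild-type colon (SD, n = 5). Of 20 goblet cell genes 18 fell, also adjusted over the list alone (camera adjusted p = 9.9e-09), with adjusted p = 0.17 with an estimated correlation, and Klk1 and Creb3l1 reached 1653 and 1549. All 20 smooth muscle genes fell, also adjusted over the list alone (camera adjusted p = 3e-17), with adjusted p = 0.052 with an estimated correlation, and Mylk and Smtn reached 2271 and 1182. All 16 B and plasma cell genes fell, also adjusted over the list alone (camera adjusted p = 1.7e-07), with adjusted p = 0.17 with an estimated correlation, and Spib and Cr2 reached 40.5 and 14.6. Of 31 fatty acid oxidation genes 21 fell and 2 rose, and 23 fell and 2 rose adjusted over the list alone (camera adjusted p = 5.9e-06), with adjusted p = 0.15 with an estimated correlation.

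Interferon-stimulated genes were not called as a list (camera adjusted p = 0.77): 4 of 26 rose and 3 fell, and 1 rose adjusted over the list alone. The median of 0.103 joins opposite directions, 0.809 in females alone and -1.03 in males alone. The median interaction with sex was -1.76 (camera adjusted p = 3.8e-07), with adjusted p = 0.99 with an estimated correlation. Usp18 went from 657 ± 643 to 2889 ± 1840 and Gbp6 from 603 ± 366 to 1629 ± 893, and both calls were lost in males alone. The call of Gbp6, a log2 fold change of 1.49, was also lost without wild-type replicates 1 and 3 (1.27 and 1.31). Camera called 24 lists, of which the Wnt target, stem cell and enteric neuron lists held with an estimated correlation (adjusted p = 0.036 each), and other splits of the libraries called up to 26. Fry called 27 lists, and the median, the mean and the test differed in sign for 6.

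Of the genes called against wild-type colon, 3426 were higher and 3649 lower in both tumour genotypes, and 54 went opposite ways. Both comparisons use the same 5 wild-type libraries. Independent lists of these sizes would share 1095 and 1184 genes. In 100 simulations of unchanged groups, the residuals of whole libraries were drawn either with or without replacement, and the second scheme was added after the first was seen. With replacement, 99 simulations shared no gene and 1 shared 5916, against 7075 observed, while none shared a gene without replacement. Unchanged groups yield few calls by design, so these counts do not measure how much the shared controls add to the 7075. Pearson's r of the log2 fold changes, across genes, was 0.906, against simulated medians of 0.642 and 0.604. The highest simulated r was 0.942 with replacement and 0.871 without, so r lay within the range of the first scheme. The covariance was 1.91, against simulated medians of 0.0694 and 0.0638, which leaves 1.84 and 1.85, and the highest simulated covariances were 0.591 and 0.168. With the wild-type libraries split between the comparisons, r lay between 0.812 and 0.884 and 4397 to 4943 genes shared a direction.

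The third comparison asked how the loss of Tgif1 and Tgif2, as labelled, changed Apc tumours. The lists of goblet cell, colonocyte, enteroendocrine, xenobiotic metabolism and protease genes were called as lower in Apc/Tgif tumours, and those of interferon-stimulated and mast cell genes as higher. None of these calls held with an estimated correlation, and only 12 of 26 colonocyte, 10 of 20 enteroendocrine and 6 of 12 mast cell genes passed. Krt15, a keratin of basal and progenitor cells, went from 467 ± 528 normalized counts (SD, n = 7) to 31660 ± 22400 (SD, n = 7) and rose by 6.73 (SE 0.628, limma adjusted p = 1.75e-06). Clca4a, a chloride channel accessory protein of colonocytes, went from 14680 ± 8560 to 751 ± 619 and fell by 4.47 (SE 0.506, limma adjusted p = 1.47e-05). There were 1453 genes higher and 1615 lower among 18445, or 1080 and 1849 with equal totals, and 431 and 788 of the former differed by over 2-fold. These counts come from a fit with 1 genotype effect for both sexes. Of 4448 genes called in females alone, 1680 were also called in that fit, and of 3202 called in males alone, 1605 were. Each sex alone has fewer libraries, and agreement of direction between the sexes was not tested. The counts therefore cannot be read as an effect common to both sexes. Of the 1453 higher genes, 830 were also higher than in wild-type colon and 99 lower. Of the 1615 lower genes, 932 were also lower than in wild-type colon and 204 higher.

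The other highest genes were Csprs (15.1 to 460), St6galnac1, a sialyltransferase of mucins (12.1 to 412), Agr3 (19.8 to 284) and the interferon-inducible genes Ifi27l2a (88.1 to 1368) and Mx2 (27.3 to 269). The lowest included 3 genes of the X chromosome: Bex4 went from 157 ± 85.7 to 1.55 ± 1.32, Rps6ka6 from 351 ± 270 to 4.57 ± 4.06 and Gspt2 from 154 ± 39.3 to 5.46 ± 4.65. Wild-type colon held 229, 116 and 165 normalized counts of them. Hsd3b3, a steroid dehydrogenase with close paralogs, went from 393 to 16.9, and Apob, the apolipoprotein of chylomicrons, from 1525 to 87.7.

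Of 20 goblet cell genes 17 fell, and 19 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.3e-11), with adjusted p = 0.33 with an estimated correlation. Zg16, a lectin of goblet cell mucus, went from 18970 to 2406 and Capn9 from 540 to 103. Of 26 colonocyte genes 12 fell, and 13 fell and 2 rose adjusted over the list alone (camera adjusted p = 2e-05), with adjusted p = 0.39 with an estimated correlation, and Krt20 went from 16590 to 2074. Of 20 enteroendocrine genes 10 fell, and 13 adjusted over the list alone (camera adjusted p = 1.3e-06), with adjusted p = 0.33 with an estimated correlation, and Cpe went from 813 to 317 and Nkx2-2 from 12.6 to 2.05. Of 26 xenobiotic metabolism genes 13 fell and 2 rose, and 16 fell and 2 rose adjusted over the list alone (camera adjusted p = 4e-05), with adjusted p = 0.39 with an estimated correlation, and Ces2e went from 2015 to 198 and Cyp2c55 from 2475 to 48.9. Of 16 pan-epithelial genes 1 rose and none fell, and none passed adjusted over the list alone (camera adjusted p = 0.86). The calls of Krt20 and Cyp2c55 were lost in females alone.

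Among proteases of the matrix and the plasminogen system 11 of 18 fell, and 13 adjusted over the list alone (camera adjusted p = 7.6e-08), with adjusted p = 0.33 with an estimated correlation. Mmp13, a collagenase, went from 15050 ± 11600 to 1368 ± 987. Of 23 neutrophil and inflammation genes 7 fell, and 14 adjusted over the list alone (camera adjusted p = 4e-06), with adjusted p = 0.33 with an estimated correlation, and the cytokines Il6 and Il11 went from 194 to 9.48 and from 1343 to 140. Of 24 glycolysis and hypoxia genes 14 fell, and 19 adjusted over the list alone (camera adjusted p = 6.5e-10), with adjusted p = 0.33 with an estimated correlation, and Eno1 went from 14440 to 9201 and Car9 from 2539 to 654. Of 24 fibroblast and matrix genes 9 fell and 1 rose, and 12 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00021), with adjusted p = 0.39 with an estimated correlation, and Tnc went from 7008 to 2875 and Pdpn from 1068 to 606. Of 21 retinoid genes 7 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.011), with adjusted p = 0.33 with an estimated correlation, and Dhrs9, a retinol dehydrogenase, went from 2024 to 227 and Rarg from 1065 to 692. The calls of Pdpn in males alone and of Rarg in females alone were lost. Of 20 enteric neuron and glia genes 4 fell, also adjusted over the list alone (camera adjusted p = 0.0057), with adjusted p = 0.39 with an estimated correlation.

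Of 26 interferon-stimulated genes 18 rose, and 19 adjusted over the list alone (camera adjusted p = 2.2e-10), with adjusted p = 0.39 with an estimated correlation. Their median interaction with sex was 1.41 (camera adjusted p = 0.0014), with adjusted p = 0.71 with an estimated correlation. Irf7, which drives interferon transcription, went from 980 ± 259 to 6057 ± 3790, while wild-type colon held 6096 ± 4990. Of 12 mast cell genes 6 rose, and 9 adjusted over the list alone (camera adjusted p = 0.00036), with adjusted p = 0.36 with an estimated correlation, and Tpsb2, a tryptase with a close paralog, went from 98.5 to 574 and Ms4a2 from 17.9 to 123. Of 23 macrophage and dendritic cell genes 9 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0063), with adjusted p = 0.42 with an estimated correlation. C1qa went from 1497 to 2288, while Arg1, an arginase of macrophages, went from 2875 to 910. The macrophage list was not called in females alone, where its median went from 0.47 to -0.0561. The calls of Tpsb2, C1qa and Arg1 were lost in females alone. Of 17 stem cell genes 6 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.023), with adjusted p = 0.33 with an estimated correlation, and Hopx went from 2986 to 5737 and Fstl1 from 6726 to 3834. The median log2 fold change of that list was 0.293, and it lost its call without Apc tumour replicate 6 (0.278) and without Apc/Tgif tumour replicate 5 (0.263). No single ribosomal protein gene passed, although camera called that list as higher (adjusted p = 0.0018), with adjusted p = 0.86 with an estimated correlation, and the call was lost without Apc/Tgif tumour replicate 2, where the median went from 0.23 to 0.126. Acetyl-CoA metabolism genes were not called (camera adjusted p = 0.43), with 5 of 36 higher and 4 lower, also adjusted over the list alone.

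None of the 15 lists called between the tumour genotypes held with an estimated correlation, and other splits of the 14 tumours called up to 22 lists, so these lists describe the libraries at hand. In females alone, 9 of the lists described above lost their call. The median of the enteric neuron list stayed about the same (-0.69 with all libraries, -0.695 in females), and those of the stem cell (0.293 to 0.236) and colonocyte (-0.959 to -0.723) lists moved little. The medians of the mast cell (1.38 to 0.745), enteroendocrine (-1.18 to -0.419), glycolysis and hypoxia (-0.534 to -0.184), retinoid (-0.486 to -0.094) and xenobiotic (-1.08 to -0.113) lists moved further towards 0, and that of the macrophage list changed sign. In males alone the ribosomal list lost its call (0.23 to 0.035). Each sex alone has fewer libraries, so a lost call by itself does not show a difference between the sexes. Of the lists lost in females, camera called the interaction with sex for glycolysis and hypoxia (adjusted p = 8.2e-05), xenobiotic (0.0011), macrophage (0.0083) and enteroendocrine (0.0085) genes. It also called the mast cell, colonocyte and retinoid lists (0.013 each). The stem cell and enteric neuron lists were not called (0.7 and 0.43). None of these interactions held with an estimated correlation (adjusted p = 0.33 at the lowest). Between the tumour genotypes fry called 18 lists, and the median, the mean and the test differed in sign for 5. The largest number of genes in another split was 1433, against 3068 here.

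**Figure D3:**
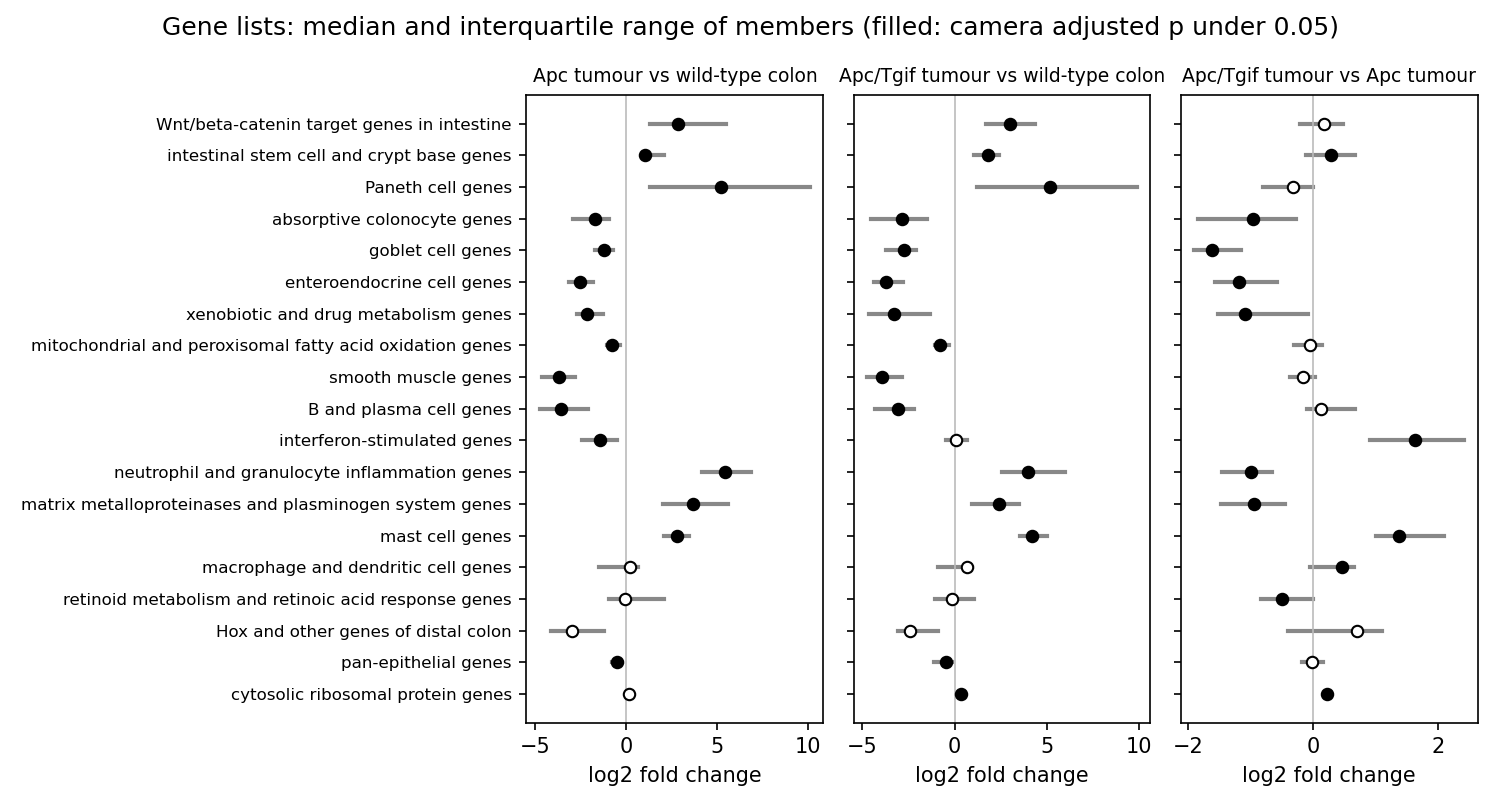
Median (point) and interquartile range (bar) of the log2 fold changes of the members of 19 gene lists in the 3 comparisons; filled points have a camera adjusted p under 0.05 and the third panel has a narrower axis. Goblet cell genes have a median of -1.61 and interferon-stimulated genes one of 1.64 between the tumour genotypes.

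**Figure D4:**
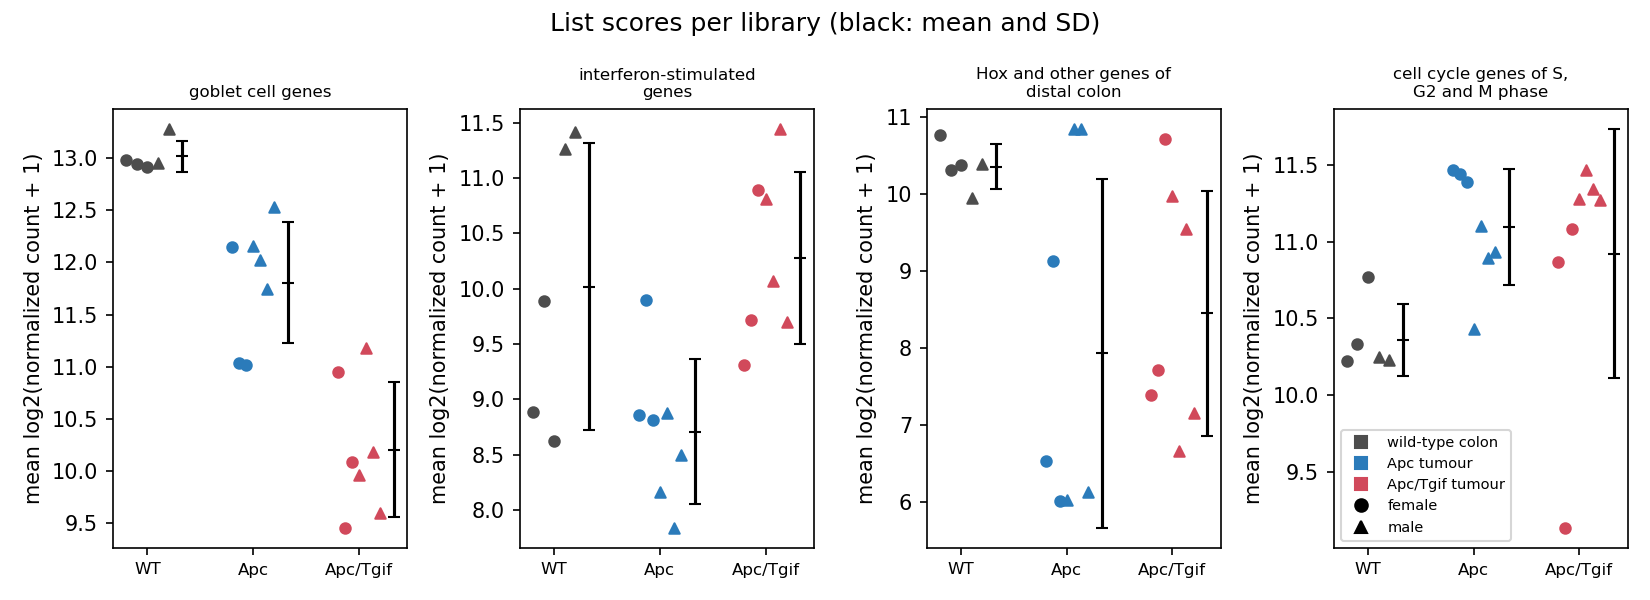
Mean log2(normalized count + 1) of the members of 4 gene lists in each library, with the group mean and SD in black, colour for group and symbol shape for sex; the axes do not start at 0. Interferon scores lie at 11.26 and 11.42 in the male wild-type libraries and between 8.63 and 9.88 in the female ones.

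Whether these effects differed by sex was tested last. Between Apc/Tgif and Apc tumours the difference depended on sex in 4352 genes. The log2 fold change between the genotypes was higher in males than in females for 2148 of them and lower for 2204. Serpina3m, a serpin with close paralogs, had means of 9.71 and 161 normalized counts in female and male Apc tumours and 165 and 4.56 in female and male Apc/Tgif tumours. Khk, ketohexokinase, had 118 and 271 in the former and 518 and 186 in the latter, and Fam98c had 663, 1692, 2812 and 1369 in the same order. The count was 2731 without Apc tumour replicate 2 and 1743 with a smooth muscle score as covariate. The third principal component followed the same pattern of genotype and sex in all 14 tumour libraries, and the GC content trend of the libraries did so apart from Apc tumour replicate 4 and Apc/Tgif tumour replicate 5. Batch, date and lane are not given in the sources used here, so a batch with that pattern and a sex difference cannot be told apart.

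Against wild-type colon the effect of the Apc/Tgif genotype differed by sex in 628 genes, among them Pdzd7, Dcxr and Mmgt1. Without wild-type replicate 4, Dcxr and Mmgt1 no longer passed (interactions of -1.15 and 1.25). Dcxr also lost its call without the GC content and length trend (-0.50) and without the 3 libraries high in Rn45s (-1.22). Removal of those 3 libraries left 1 male wild-type library, so a lost call there cannot be tied to Rn45s. The count of 628 rested on single libraries. It was 124, 26, 5 and 29 without wild-type replicates 1, 3, 4 and 5, it was 366 and 1024 without Apc tumour replicates 3 and 4, and it was 315, 243, 1801, 235 and 278 without Apc/Tgif tumour replicates 2, 4, 5, 6 and 7. The effect in Apc tumours differed by sex in 2 genes, Sfxn3 and Pdzd7, with 2134 genes at an unadjusted p under 0.05 by limma, and Ppid had the next smallest p (limma adjusted p = 0.0852, an interaction of -1.48). Ppid passed without wild-type replicates 2 and 5 (-1.51 and -1.76), without Apc tumour replicate 1 (-1.54) and without Apc/Tgif tumour replicate 2. There the count was 40, 4 and 5 without wild-type replicates 2, 3 and 5, it was 21 and 7 without Apc tumour replicates 1 and 4, and it was 5 without Apc/Tgif tumour replicate 2. Without the 3 libraries high in Rn45s, with 1 male wild-type library left, neither Sfxn3 nor Pdzd7 kept its call (interactions of 1.85 and 3.88).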

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

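The tests of a single aberrant library, of a batch that follows genotype and sex, of a wrong genotype label, of a block of linked strain differences and of a loss of epithelial cells were chosen only after the result was seen.

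Many genes showed a difference between Apc/Tgif and Apc tumours that depended on sex (4352, by the interaction test of limma). Random assignment of the sexes within each tumour genotype reached as many in 1 of 100 cases, the real one, and 2055 at most otherwise. Chance is thus unlikely, though 100 cases cannot exclude it. The assignment with 2055 exchanged Apc/Tgif replicates 3 and 5. In fits of the 15983 genes with a known GC content and length, removal of each library's trend on both took the count from 4020 to 3155. Spearman's rho of the interaction with GC content, across these genes, went from -0.402 to 0.0112. Leaving out any 1 library gave at least 2731, the value without Apc tumour replicate 2. This argues against either as the whole cause. All 14 tumour libraries lay on the side of the third principal component set by their genotype and sex. A batch with that pattern and a sex difference cannot be told apart, because the labels give no batch.

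Tgif2 was higher in the tumours labelled null for it. The highest Tgif1 value of these tumours was 23.5% of the lowest in the Apc tumours, which argues against an exchange of tumours between the 2 genotypes. Tgif1 values cannot check the Tgif2 part of the label, which stays open. Genes within 2 Mb of Tgif1 and Tgif2, pooled over both loci, were called no more often than elsewhere (odds ratio 0.82, upper 95% limit 1.49). The pooled share argues only against linked strain differences that change many genes across both windows. It cannot decide on a block at either locus alone, or on a block that changes few of its genes, so these stay open. Dlgap1, chosen after its values were seen, was a called neighbour of Tgif1. It ends at 70821413 on chromosome 17, beyond the downstream end of Tgif1 at 70844205, since Tgif1 lies on the minus strand. It lay between 691 and 1042 normalized counts in the 7 Apc/Tgif tumours and between 83.3 and 174 in the Apc tumours (log2 fold change 2.92, limma adjusted p = 2.57e-09). A difference confined to the close surroundings of Tgif1 stays open. Transcripts that remain after the deletion stay open, since the values per gene hold no exons. No biological explanation was tested.

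The goblet cell and colonocyte lists were called as lower in Apc/Tgif than in Apc tumours, with 17 of 20 and 12 of 26 genes. Neither call held with an estimated correlation (camera adjusted p = 0.33 and 0.39), and the colonocyte call was lost in females alone. With the distal colon score as covariate the median log2 fold change of the goblet list was -1.53. That score overlapped between Apc (7.927 ± 2.27, SD, n = 7) and Apc/Tgif tumours (8.447 ± 1.59), so the covariate could change little. The small intestine score, not used as covariate, was 8.127 ± 0.717 and 7.054 ± 0.454 in the same order. Hoxb13 had 4679 ± 3500 and 7639 ± 693 normalized counts. Position along the colon therefore stays open. After removal of the GC content and length trend the median of the goblet list was -1.56. The median of the pan-epithelial list was -0.0204, with a lower quartile of -0.17, which argues against a general loss of epithelial cells. The Tgif genotype stays open as a biological explanation.

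Chance is an unlikely source of the numbers of genes called in all 3 comparisons, though 100 splits cannot exclude it. In each, only the real split, 1 of 100, gave as many genes: 9054 against 6770 at most in Apc tumours and wild-type colon, 9284 against 5553 in Apc/Tgif tumours and wild-type colon, and 3068 against 1433 between the tumours. Other splits can keep part of the real difference between the groups, so for the numbers of lists this test cannot decide and chance stays open. As many lists were called in 10, 12 and 37 of 100 splits, with 33, 26 and 22 at most in another split against 26, 24 and 15. Males and females differed in 1537 genes among Apc tumours and 1391 among Apc/Tgif tumours, and only the real split of 35 gave as many in each (1, with 909 and 492 at most in the others).

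The number of gene lists whose effect differed by sex was 18, 7 and 15 in the 3 comparisons, none of which held with an estimated correlation. Between the tumours the cell cycle list had the smallest camera adjusted p (1.8e-09, or 0.65 with an estimated correlation). Its median interaction was 1.72, with 21 of 33 genes higher and 0 lower. Apc/Tgif replicate 2, a female, had a cell cycle score of 9.133, against 10.87 to 11.47 in the other Apc/Tgif tumours. For the comparison of the tumours, 37 of 100 assignments of the sexes gave as many lists, and 23 was the most in another, so chance cannot be excluded. The number of genes was 2 for Apc tumours and 628 for Apc/Tgif tumours against wild-type colon. The interaction on the log2 scale, males minus females, was 1.78 for Sfxn3 and 4.42 for Pdzd7 in Apc tumours, 5.03 for Pdzd7, -1.28 for Dcxr and 1.21 for Mmgt1 in Apc/Tgif tumours against wild-type colon, and -8.42 for Serpina3m, -2.65 for Khk and -2.36 for Fam98c between the tumours.

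Single libraries stood apart from their group in 31 of 357 groups of values, by the gap to the nearest library as a share of the group's range. Chance gives about 5% of groups. Apc/Tgif replicate 2 was the highest for Tgif1 (gap 0.644), Cpe (0.648) and the glycolysis and hypoxia score (0.572), and the lowest for Smtn (0.598) and the scores of cell cycle (0.745), fatty acid synthesis (0.617) and cholesterol synthesis genes (0.587). Apc/Tgif replicate 5 was the lowest for Apc (0.653), Serpinb11 (0.586) and Agr3 (0.591) and the highest for the share of Rn45s, at 9.35% of its total (0.978), and of the 10 most abundant genes, at 17.8% (0.919). Apc/Tgif replicate 1 was the highest for the small intestine score (0.586) and the xenobiotic score (0.78). Apc replicate 6 was the lowest for Defa17 (0.608), Defa24 (0.664) and the Wnt target score (0.579) and the highest for Pln (0.602). Apc replicates 5, 4 and 7 stood apart for Csprs (0.636), Cpe (0.822) and Eno1 (0.585). Wild-type replicate 4 was the highest for Vip (0.822) and the erythroid score (0.772), and replicate 3 for St6galnac1 (0.834) and the scores of cell cycle genes (0.795) and proteases (0.784). Wild-type replicate 5 was the highest for the goblet score (0.794) and replicate 1 the lowest for Cr2 (0.711). Defa24, Cxcl3 and Defa22 were above 0 in 1 wild-type library each (gap 1).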

How the results depend on the processing

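Settings added after seeing the data were equal totals, removal of the GC content and length trend, the distal colon covariate, quality weights, means per group and sex, and removal of the 3 libraries high in Rn45s; settings planned for gene counts were also added for the overlap, the lists and the interaction where not planned for them. Count tests, their size factors and voom were not run, since the table holds no counts.

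Counts of genes changed by over 1.5 times in few settings. Over 2-fold there were 1962 higher and 2673 lower genes in Apc tumours against wild-type colon, 1996 and 2912 in Apc/Tgif tumours against wild-type colon, 431 and 788 between the tumours, and 3622 shared by both tumour comparisons, fewer by construction. In males alone 3039 genes were lower in Apc tumours than in wild-type colon, and in females alone 2230 were higher in Apc/Tgif than in Apc tumours; the cause was not tested. With split wild-type libraries the shared genes numbered 4696, 4694 and 4397 in 3 of 10 splits, with fewer libraries per comparison. With 1 library left out, the counts ranged from 3942 to 4831 and from 4195 to 4919 (Apc tumours, higher and lower), from 4160 to 4831 and from 4315 to 4764 (Apc/Tgif tumours), from 1191 to 1644 and from 1334 to 1809 (between the tumours) and from 6403 to 7574 (shared). Equal totals moved the median of all genes from -0.01 to 0.19 in Apc tumours and from 0.0016 to 0.15 in Apc/Tgif tumours against wild-type colon.

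The sex interaction depended most on the setting. Between the tumours it gave 1743 genes with the smooth muscle covariate, 2722 over 2-fold and 7814 with quality weights, and from 2731 to 4909 with 1 library left out. For Apc/Tgif tumours against wild-type colon it gave 378 with only the groups compared, 3650 with weights, 9 without the libraries high in Rn45s, and from 5 to 1801 with 1 library left out. Removal of the GC content and length trend took it from 561 to 88 in fits of the same 15983 genes, so that count depended on the trend. For Apc tumours it gave 11, 7 and 1283 with only the groups compared, the distal colon covariate and weights, 0 without the libraries high in Rn45s, and from 2 to 40 with 1 library left out. Beyond the tests and settings given, the cause was not tested.

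No named gene changed direction with a call, and 12 of their calls were lost and 14 gained across settings. Of the lists, 5 changed the direction of the camera test. The median of interferon-stimulated genes in Apc/Tgif tumours against wild-type colon went from 0.103 to -1.03 in males alone, and that of cell cycle genes between the tumours from -0.152 to 0.622 in males alone. In females alone the median of macrophage genes between the tumours went from 0.47 to -0.0561. The medians of retinoid and unfolded protein response genes kept their sign there, from -0.486 to -0.094 and from -0.143 to -0.493, while the direction of the test changed. The cause was not tested. An estimated correlation ended 56 list calls. Depth limits genes near 10 normalized counts.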

Other observations

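The test of genes near Pdzd7 and that of the X chromosome replaced earlier versions, which ran on the genes that had raised the question (for X, 2 of 2 genes, Fisher's exact p = 0.00104); the genes, the windows and the limits of both were chosen after their values were seen.

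The mean of the distal colon genes split both tumour groups. Hoxb13, a member of that list, did not split the 7 Apc/Tgif tumours, where it lay between 6540 and 8720 normalized counts. The mean log2 value of the distal colon list lay between 9.94 and 10.77 in wild-type libraries. It lay between 6.004 and 6.53 in Apc replicates 1, 3, 4 and 7 and between 9.13 and 10.84 in the other 3, and between 6.66 and 7.71 in Apc/Tgif replicates 1, 2, 5 and 7 and between 9.55 and 10.71 in the other 3. Interferon-stimulated genes had scores of 11.26 and 11.42 in the male wild-type libraries and between 8.63 and 9.88 in the female ones. Among TGF-beta and Smad response genes, 16 of 26 rose and 3 fell in Apc tumours against wild-type colon, and 16 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.16 with an estimated correlation), and 4 rose and 3 fell between the tumours, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.69).

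With limits of 15 and 30 normalized counts, 2 genes were near 0 in all 7 Apc/Tgif tumours and present in all 12 other libraries: Gspt2 and Rps6ka6, both on the X chromosome. No gene had the same pattern with the Apc tumours near 0. The hypothesis that lower genes cluster on X was tested on the other genes lower by over 2-fold, without these 2 and without Bex4, also on X and among the lowest genes already seen, of which 34 of 743 lay on X, or 4.58% against 3.22% of the 15980 genes tested with a position (odds ratio 1.47, lower 95% limit 1, upper limit 2.11, Fisher's exact p = 0.042). The excess is small and may reflect a weak clustering that leaves most of the lower genes elsewhere.

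In wild-type colon Pdzd7 had means of 418 normalized counts in females and 18.7 in males, Sfxn3 1427 and 656, and Wnt8b 117 and 0. All 3 lie on chromosome 19, Pdzd7 from 45026906 to 45045717, Sfxn3 from 45047503 to 45056383 and Wnt8b from 44493472 to 44514273. A candidate explanation is a local difference between the mice at this locus. Of the other 23 genes within 1 Mb, 6 had an unadjusted limma p under 0.05 between the sexes, against 12.7% elsewhere (odds ratio 2.42, 95% limits 0.78 and 6.44, Fisher's exact p = 0.0635), so this test leaves the local difference open. In the tumours Pdzd7 had 96.4 in females and 94.9 in males with Apc alone and 82.9 and 117 with Apc/Tgif, and Sfxn3 had 1060 and 1674, and 1823 and 1341. These argue against a sex difference common to all 3 groups. A sex difference of normal colon alone and a local difference cannot be told apart for these 3 genes in 5 mice.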
